A study of Homo sapiens with 18 samples.

How the data were processed

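The series holds RNA sequencing of 18 libraries from SW48 colon adenocarcinoma cells in 6 groups of 3. Cells received control siRNA or siCHD4, alone, with siDNMT1 or with 50 nM decitabine, on the schedules given in the report. Per the labels, cells were grown in L-15 medium with 10% serum, RNA was extracted with Trizol or an RNeasy kit (which library had which is not given), and stranded libraries were made from 1 µg of total RNA after ribosomal RNA removal. Groups and replicate numbers were taken from the library titles. The numbers 0, 1 and 2 were not taken to pair libraries across groups: the residuals of libraries with the same number correlated between -0.31 and 0.126.

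The deposited table gives FPKM computed by the authors, 1 column per library. Per the submitters' processing notes, reads were aligned with TopHat2 2.0.9 to hg19 and expression was computed with Cuffdiff 2.1.1. The gene annotation, the filters and the scaling between libraries are not given in the sources used here. The table has 23599 entries, of which 28 (0.119%) carry a date in place of a gene name and were left out. Of the 23571 named genes 3747 are listed at 0 in every library. All 18 value columns were used. Read counts and read totals were not used here, so no counting intervals can be given. The relative depth of each library was read from the smallest step between the values of low genes, which is the worth of 1 fragment.

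Values were taken to log2(FPKM + 1), which understates the fold change of low genes. Genes with at least 1 FPKM in at least 3 of the 18 libraries were tested, which left 12809. A linear model with 1 mean per group was fitted over all 18 libraries (12 residual degrees of freedom) with limma 3.58.1 in R 4.3.3, using empirical Bayes moderation with a trend in the mean. The p-values were adjusted by the Benjamini-Hochberg method over all genes tested in a comparison, and genes with an adjusted p below 0.05 are called higher or lower. All adjusted p-values of genes come from this model, and all are two-sided. The comparisons were siCHD4 with control siRNA in each of the 3 backgrounds, each of the other 4 groups that received siDNMT1 or decitabine with control siRNA alone, and 3 differences between the siCHD4 effects. The siCHD4 comparisons within a background share a schedule, and the comparisons with control siRNA alone do not, so treatment and schedule cannot be told apart in those. Genes listed at 0 throughout a group are given as listed, with no fold change. Calls of CHD4 and DNMT1 are given with an exact two-sided permutation test of the FPKM values.

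Genes silent in the control were counted as those with a mean under 0.5 FPKM in the control group and called higher, beside the opposite count of genes called lower whose treated mean was under 0.5 FPKM. Overlaps of calls were tested with Fisher's exact test (two-sided) over the tested genes. For siDNMT1, decitabine and siCHD4 alone, which share the control libraries, 100 simulated pairs of unchanged groups were set against the same controls.

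The 23 gene lists were NuRD complex, CHD remodeler family, DNA methylation machinery, genes often hypermethylated in colorectal cancer, cancer-testis and germline genes, interferon-stimulated genes, p53 targets, mitotic genes, DNA replication genes, intestinal differentiation genes, Wnt and intestinal stem cell genes, mesenchymal transition genes, neuronal genes, imprinted genes, endoplasmic reticulum and amino acid stress genes, cholesterol synthesis genes, mitochondrially encoded genes, replication-dependent histone genes, ribosomal protein genes, and markers of fibroblasts, blood cells, endothelial cells, and neural and glial cells. They were written from general knowledge, so some genes stand in more than 1 list. The 19 lists with at least 5 tested genes were tested with limma's camera at a preset correlation between genes of 0.01, with adjustment over the lists of a comparison, and again with an estimated correlation and with fry, which asks whether the genes of a list move one way on balance. The other 4 lists were described without a test.

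The genes named are CHD4 and DNMT1, genes among the 10 largest called changes in each direction for the 3 siCHD4 comparisons and the 5 largest for the others, with the libraries of the groups fully separated (not required for differences between effects), and genes among the 4 members with the smallest p of a described list. The comparisons, tests, lists, the rule for named genes and the alternatives were fixed before the data were examined, except the 3 alternatives and the tests that the closing section gives as chosen later. From these named genes, those whose call held with each single library left out were preferred in the text, a choice made after the values were seen.

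The alternatives were a pseudocount of 0.1, no filter, a filter at 5 FPKM, rescaling by the median ratio, quantile normalization, the replicate number as a block, library weights, a fit on the compared groups only, limits of 0.1 and 1 FPKM for silent genes, and each library left out in turn. Gene positions, lengths and GC content came from a GENCODE annotation of GRCh37, matched by symbol for 20492 of 23571 genes (86.94%). The procedure was tested on data simulated with the spread of the fit over all libraries, equal between libraries. Changes added to 200 of 12809 genes were recovered for 41.8% at a log2 change of 0.5, 82.1% at 1 and 97.0% at 2. Of 12609 unchanged genes 4 were called. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.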

Results

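RNA sequencing was used to measure gene expression in SW48, an established human colon adenocarcinoma cell line, after depletion of CHD4, with and without siRNA against DNMT1 or decitabine. CHD4 is the ATPase of the nucleosome remodelling and deacetylase (NuRD) complex, DNMT1 is the maintenance DNA methyltransferase, and decitabine is a cytidine analogue that is built into DNA and traps DNA methyltransferases. The 18 libraries formed 6 groups of 3: control siRNA or siRNA against CHD4 (siCHD4), each given alone, together with siRNA against DNMT1 (siDNMT1), or together with 50 nM decitabine. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The siRNA given alone was applied on days 1, 3 and 6 with RNA taken on day 8. With siDNMT1 (days 1, 3 and 5) the test siRNA was applied on days 7 and 8 and RNA was taken on day 11, and with decitabine (days 1, 2 and 3) it was applied on days 1 and 2 and RNA was taken on day 5. The series presents CHD4 as a target for epigenetic therapy, so the design asks what loss of CHD4 does alone and on top of a treatment directed at DNA methylation.

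Expression was listed as FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library) for 23571 named genes, of which 12809 were tested. Read totals are not listed. The most frequent ratio of values to control siRNA replicate 0, among 6364 low genes, was taken as the relative worth of 1 fragment. It was 4.11-fold in control siRNA plus decitabine replicate 0 (2.04 on the log2 scale) and lay between -0.74 and 0.16 on that scale in the other libraries. That library was therefore the shallowest by this measure. Each library listed 11477 to 12502 genes at 1 FPKM or more. Log2 values of libraries of the same group correlated across genes with r between 0.929 and 0.980, and 0 pairs of libraries held identical values. Groups were not fully separated by these correlations: control siRNA replicate 2 had r = 0.967 and 0.965 with siCHD4 replicates 0 and 1, against 0.966 and 0.964 with control siRNA replicates 0 and 1. After group means were removed, the residuals of control siRNA replicate 2 correlated with those of siCHD4 replicates 0 and 1 (0.173 and 0.229). Those of siCHD4 replicate 2 correlated with those of control siRNA replicates 0 and 1 (0.197 and 0.196). Among these 6 libraries CHD4 was lowest in siCHD4 replicate 2 (23.2 FPKM) and highest in control siRNA replicate 2 (68.2 FPKM), as the labels have it.

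The targeted transcripts were examined first. CHD4 (chromosome 12, 6679248 to 6723690, minus strand, GRCh37) fell from 62.8 ± 4.78 FPKM with control siRNA to 31.3 ± 7.87 with siCHD4 (mean ± SD, n = 3 in each group; log2 change -1.01, SE 0.14, limma adjusted p = 0.000201), which is 49.9% of the control. With siDNMT1 it fell from 68.2 ± 5.19 to 28.4 ± 1.12 FPKM (log2 change -1.24, adjusted p = 7.64e-06). With decitabine it was 76.2 ± 8.17 FPKM with control siRNA and 54.9 ± 2.06 with siCHD4 (log2 change -0.46, adjusted p = 0.0752), a difference that did not pass the threshold over all genes although the 3 siCHD4 libraries lay below the 3 controls. Without control siRNA plus decitabine replicate 0 this change was -0.55 with adjusted p = 0.0449. The CHD4 change with siDNMT1 was larger than that with decitabine (difference -0.77, adjusted p = 0.0289), whereas the differences from siCHD4 alone did not pass the threshold (-0.23 with siDNMT1, adjusted p = 0.561; 0.55 with decitabine, adjusted p = 0.209). DNMT1 (chromosome 19, 10244018 to 10341962, minus strand) fell from 44.7 ± 0.892 to 12.3 ± 1.15 FPKM with siDNMT1 (log2 change -1.78, adjusted p = 2.32e-08) and was at 27.1% of the control with siCHD4 plus siDNMT1. It changed by 0.20 with decitabine (adjusted p = 0.222) and by -0.08 with siCHD4 (adjusted p = 0.639). An exact two-sided permutation test of each siCHD4 and siDNMT1 depletion gave p = 0.1, the smallest value that 3 against 3 libraries allow.

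**Figure D1:**
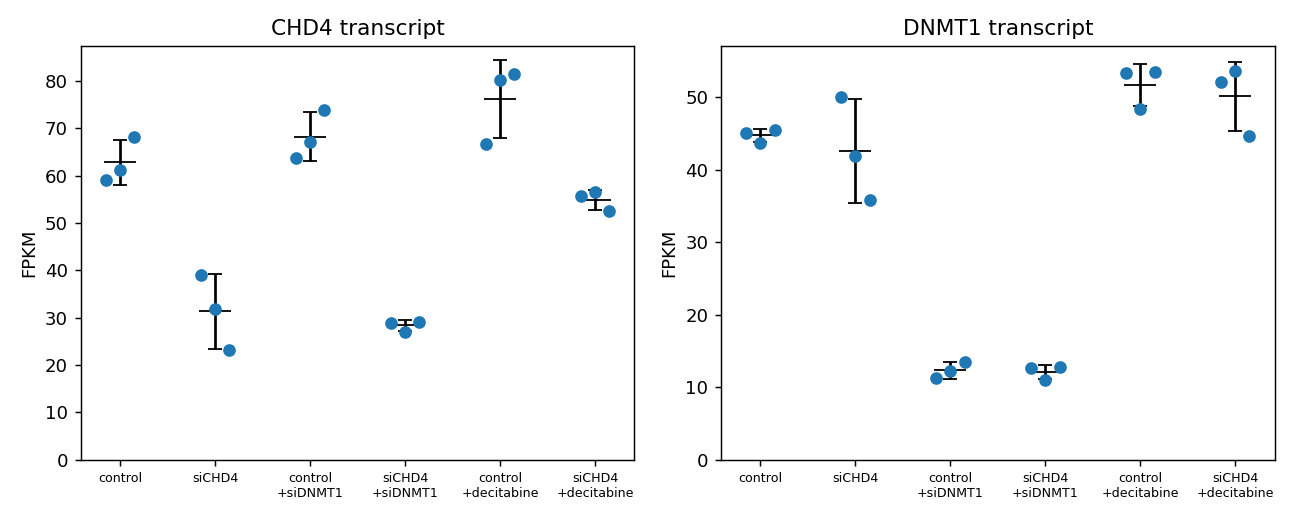
FPKM of CHD4 and of DNMT1 in each of the 18 libraries (points), with the mean and SD of each group of 3 (horizontal line and bar). CHD4 averaged 31.3 FPKM with siCHD4 alone, 28.4 with siDNMT1 and 54.9 with decitabine, and DNMT1 averaged 12.3 FPKM in the control siRNA plus siDNMT1 group.

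Depletion of CHD4 alone raised a small set of genes far above the control. TEX19, a germ cell gene (chromosome 17, 80317123 to 80321651, plus strand), rose from 0.316 ± 0.160 to 57.6 ± 9.61 FPKM (log2 change 5.47, adjusted p = 8.26e-10). BST2, the antiviral membrane protein tetherin (chromosome 19, 17513748 to 17516439, minus strand), rose from 0.102 ± 0.0885 to 16.7 ± 4.93 FPKM (log2 change 3.97, adjusted p = 7.20e-07), and LGALS1, which encodes galectin-1, rose from 3.35 ± 1.66 to 57.2 ± 11.9 FPKM (log2 change 3.79, adjusted p = 1.40e-07). DHRS2, a short-chain dehydrogenase, rose from 8.69 ± 7.11 to 97.8 ± 15.8 FPKM, TXNIP, the thioredoxin-interacting protein, from 12.3 ± 3.66 to 125 ± 76.5 FPKM, and HIST1H1T, a testis linker histone, from 3.39 ± 1.30 to 111 ± 42.7 FPKM. Among the genes that fell, EHF, an epithelial ETS-family transcription factor (chromosome 11, 34642640 to 34684835, plus strand), went from 111 ± 4.67 to 32.4 ± 3.93 FPKM (log2 change -1.76, adjusted p = 1.40e-06). ALDH3A1, an aldehyde dehydrogenase, went from 48.9 ± 3.47 to 15.5 ± 2.50 FPKM, HAS2, a hyaluronan synthase, from 5.64 ± 1.53 to 0.865 ± 0.206 FPKM, PHGR1, a gut-expressed gene, from 6.50 ± 4.31 to 0.417 ± 0.361 FPKM, and NAPG, a vesicle fusion protein, from 121 ± 1.98 to 43.8 ± 4.11 FPKM. For each gene named here or below as passing the test in a comparison of 3 against 3 libraries, the 3 treated libraries lay on one side of the 3 controls.

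Of the gene groups fixed in advance, 11 of the 55 replication-dependent histone genes measured rose with siCHD4 and 0 fell (11 adjusted over the list alone), and 31 rose after quantile normalization. HIST1H2BG rose from 0.152 ± 0.263 to 17.6 ± 6.99 FPKM, HIST1H2AE from 0.108 ± 0.188 to 6.10 ± 1.95 FPKM and HIST1H2BI by 2.48 on the log2 scale. The list passed limma's camera test with its preset correlation (adjusted p = 5.02e-07) and lost the call at adjusted p = 0.820 with an estimated correlation. Histone genes are near-identical copies whose reads can be shared, so the value of each is uncertain. Of 33 p53 targets, 10 rose and 1 fell (11 and 2 adjusted over the list alone; adjusted p = 0.00542, and 0.327 with an estimated correlation). The cell cycle inhibitor CDKN1A rose from 22.8 ± 9.66 to 55.5 ± 15.1 FPKM, BTG2 by 0.87 and TP53I3 by 0.73 on the log2 scale. Of 44 DNA replication genes, 15 fell and 2 rose (16 and 2 adjusted over the list alone; adjusted p = 0.000328, and 0.820 with an estimated correlation). The ribonucleotide reductase subunits RRM1 and RRM2 changed by -0.42 and -0.54. Cholesterol synthesis genes fell in 7 of 26 cases and rose in 1 (8 and 1 adjusted over the list alone; adjusted p = 0.00606, and 0.139 with an estimated correlation). ACAT2 changed by -0.70 and MSMO1 by -0.60. Of 16 mesenchymal transition genes 6 rose and 2 fell (6 and 2 adjusted over the list alone; adjusted p = 0.00606, and 0.327 with an estimated correlation). The matrix protein TNC went from 0.159 ± 0.105 to 3.36 ± 0.355 FPKM and the smooth muscle actin ACTA2 from 2.43 ± 0.594 to 13.5 ± 0.940 FPKM, while S100A4 fell by 0.59 on the log2 scale. Of 14 imprinted genes 5 rose and 1 fell (5 and 1 adjusted over the list alone; adjusted p = 0.00992, and 0.327 with an estimated correlation). GRB10 changed by 1.51 and PLAGL1 by 0.64. After quantile normalization 1 imprinted gene rose and 1 fell, and 3 mesenchymal transition genes rose. With the GC trend removed 3 imprinted genes rose.

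Other lists did not pass the list test although members did. Of 13 intestinal differentiation genes 6 rose and 3 fell (6 and 3 adjusted over the list alone; adjusted p = 0.253). The differentiation keratin KRT20 went from 0.0241 ± 0.0418 to 2.37 ± 1.58 FPKM, the mucin MUC13 from 0.0846 ± 0.0766 to 1.42 ± 0.889 FPKM and the brush border protein VIL1 from 0.696 ± 0.136 to 3.28 ± 2.07 FPKM. Of 23 Wnt and intestinal stem cell genes 3 rose and 3 fell (4 and 3 adjusted over the list alone; adjusted p = 0.689). ETS2 changed by 1.33 and the cyclin CCND1 by -1.02. Interferon-stimulated genes rose in 6 and fell in 2 of 35 cases (7 and 3 adjusted over the list alone; adjusted p = 0.328). BST2 and HLA-B (0.45) were higher and CMPK2 (-1.03) lower. The de novo methyltransferase DNMT3B was the 1 of 14 DNA methylation genes that passed (0.90; list adjusted p = 0.534). Among 39 cancer-testis and germline genes 2 rose (1 adjusted over the list alone; adjusted p = 0.357). PAGE1, on the X chromosome, went from 0.163 ± 0.142 to 3.85 ± 2.52 FPKM. PAGE4, listed at 0 in the 3 control siRNA libraries, averaged 2.01 ± 1.64 FPKM with siCHD4. Its adjusted p = 0.0223 became 0.0611 and 0.0619 without control siRNA replicates 0 and 1, and 0.0650 and 0.0959 without siCHD4 replicates 1 and 2. Neuronal genes rose in 2 of 12 cases (2 adjusted over the list alone; adjusted p = 0.113), the microtubule regulator STMN3 (1.26) and the adhesion molecule L1CAM (1.15). Of 14 NuRD complex genes 3 rose and 3 fell (4 and 3 adjusted over the list alone; adjusted p = 0.829). CHD3, a paralog of CHD4, changed by 0.69, and by 0.38 without siCHD4 replicate 2. The 9 CHD remodeler genes measured held 1 that rose and 2 that fell (2 and 2 adjusted over the list alone; adjusted p = 0.829). Of 6 blood cell markers 0 passed (0 adjusted over the list alone; adjusted p = 0.930). The tested genes held 0 mitochondrially encoded genes, 0 endothelial markers and 1 neural and glial marker, which did not pass. Of 4 fibroblast markers, a list too short to test, 1 rose (1 adjusted over the list alone; median 0.43), the collagen gene COL6A3 (1.83). After quantile normalization 4 interferon-stimulated genes fell, and 3 CHD remodeler genes rose once the GC trend was removed.

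In all, 1227 genes were higher and 1244 lower with siCHD4 than with control siRNA by limma at adjusted p below 0.05, and 141 and 53 of these changed by at least 1 on the log2 scale. The 6 libraries separated completely by group for 33.5% of the tested genes, where chance gives 10%. Of 726 tested genes under 0.5 FPKM in the control, 119 were called higher, and of 484 under 0.5 FPKM with siCHD4 6 were called lower. To be tested such low genes needed 1 FPKM in 3 libraries, mostly of other groups, which favours changes away from the low level. Without that filter the counts were 247 of 7503 and 18 of 7069. The 2471 calls became 1532 and 1484 without control siRNA replicates 0 and 1, 5904 with library weights and 514 in a fit on these 6 libraries alone.

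When siCHD4 was added to siDNMT1, cancer-testis and germline genes rose. Of the 39 tested, 37 rose and 0 fell (37 adjusted over the list alone), and the list held its call with an estimated correlation (camera adjusted p = 6.71e-20, and 0.0205 with an estimated correlation). The list holds 74 genes, of which 35 were too low to be tested, so the 39 are those that are high in at least some libraries and the share is partly fixed by the filter. Without the filter 46 of the 74 were called higher and 0 lower. MAGEB6 went from 0.288 ± 0.148 to 12.6 ± 0.971 FPKM (log2 change 3.41, adjusted p = 1.30e-10) and MAGEA4 (chromosome X, 151080967 to 151093643, plus strand) from 0.384 ± 0.0842 to 10.6 ± 1.64 FPKM (log2 change 3.06, adjusted p = 1.30e-10). MAGEC2 went from 0.221 ± 0.0279 to 11.3 ± 2.38 FPKM and PAGE1 (chromosome X, 49452050 to 49460587, minus strand) from 3.98 ± 1.18 to 80.2 ± 3.44 FPKM. TEX19 rose from 0.354 ± 0.0253 to 57.1 ± 5.21 FPKM (log2 change 5.42, adjusted p = 1.90e-10). BST2 rose from 2.63 ± 0.839 to 87.4 ± 10.7 FPKM, LGALS1 from 12.0 ± 3.65 to 269.6 ± 16.3 FPKM, and TKTL1, a transketolase-like gene on the X chromosome, from 0.403 ± 0.117 to 30.3 ± 0.934 FPKM. The epithelial ETS factors ELF5 (chromosome 11, 34500338 to 34546740, minus strand) and EHF fell. ELF5 went from 40.7 ± 1.73 to 8.51 ± 0.895 FPKM (log2 change -2.14, adjusted p = 2.75e-07) and EHF from 87.8 ± 4.22 to 20.5 ± 0.664 FPKM (log2 change -2.05, adjusted p = 6.58e-08). APOBEC3G, an antiviral cytidine deaminase, fell from 7.63 ± 0.641 to 0.649 ± 0.0893 FPKM.

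Neuronal genes rose in 9 of 12 cases with 0 lower (9 adjusted over the list alone; adjusted p = 0.000269, and 0.0375 with an estimated correlation). The neuronal deubiquitinase UCHL1 went from 2.86 ± 0.554 to 9.13 ± 1.01 FPKM and BEX2 from 0.231 ± 0.0885 to 2.05 ± 0.515 FPKM. The remaining list calls in this comparison were lost with an estimated correlation. DNA replication genes fell in 37 of 44 cases and rose in 1 (37 and 1 adjusted over the list alone; adjusted p = 7.76e-13, and 0.185 with an estimated correlation). The clamp loader RFC4 changed by -1.19, RRM1 by -1.01 and the polymerase subunit POLE2 by -1.31. Ribosomal protein genes fell in 38 of 46 cases with 0 higher (40 adjusted over the list alone; adjusted p = 1.43e-11, and 0.300 with an estimated correlation). RPL14 changed by -1.09 and RPL5 by -0.74, with a list median of -0.64 that was -0.20 after quantile normalization, where 11 fell. Mitotic genes fell in 13 of 32 cases and rose in 1 (13 and 1 adjusted over the list alone; adjusted p = 0.00459, and 0.300 with an estimated correlation). Cholesterol synthesis genes fell in 12 of 26 and rose in 3 (12 and 3 adjusted over the list alone; adjusted p = 0.0130, and 0.0667 with an estimated correlation). ACAT2 changed by -1.44. Mesenchymal transition genes rose in 13 of 16 cases and fell in 1 (13 and 1 adjusted over the list alone; adjusted p = 7.02e-06, and 0.0582 with an estimated correlation). Fibronectin FN1 went from 0.330 ± 0.116 to 2.30 ± 0.0873 FPKM, while S100A4 went from 2147 ± 116 to 859.8 ± 17.8 FPKM. Imprinted genes rose in 11 of 14 cases and fell in 1 (11 and 1 adjusted over the list alone; adjusted p = 0.00238, and 0.0953 with an estimated correlation). GRB10 changed by 2.25 and MKRN3 by 1.05. Intestinal differentiation genes rose in 6 of 13 cases and fell in 1 (6 and 1 adjusted over the list alone; adjusted p = 0.0477, and 0.300 with an estimated correlation). MUC13 changed by 1.51 and HNF4A by 0.97. After quantile normalization 7 imprinted and 4 mitotic genes rose, and 1 cholesterol synthesis gene rose with the GC trend removed.

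Histone genes rose in 2 and fell in 10 of 55 cases (1 and 4 adjusted over the list alone; adjusted p = 0.0177, and 0.659 with an estimated correlation). Interferon-stimulated genes rose in 12 and fell in 5 of 35 cases without passing the list test (12 and 5 adjusted over the list alone; adjusted p = 0.0711). IFI27 went from 1.45 ± 1.05 to 20.1 ± 2.95 FPKM. Of 8 genes often hypermethylated in colorectal cancer 4 rose (4 adjusted over the list alone; adjusted p = 0.0526), namely ESR1, NDRG4, DKK1 and VIM, of which the oestrogen receptor gene ESR1 went from 0.00593 ± 0.0103 to 1.10 ± 0.0256 FPKM. Of 24 endoplasmic reticulum and amino acid stress genes 11 rose and 2 fell (11 and 2 adjusted over the list alone; adjusted p = 0.0537). The chaperone HSPA5 changed by 0.98. Of 14 DNA methylation genes 6 rose and 0 fell (6 adjusted over the list alone; adjusted p = 0.136), and 3 rose with the GC trend removed. Markers of other cell types were higher too. Of 6 blood cell markers 4 rose (4 adjusted over the list alone; adjusted p = 0.00964, and 0.0582 with an estimated correlation). The leukocyte gene PTPRC went from 0.486 ± 0.232 to 1.93 ± 0.328 FPKM. All 4 fibroblast markers measured rose, a list too short to test, with the collagen gene COL6A3 from 3.45 ± 0.198 to 20.9 ± 1.12 FPKM. Across the comparison 3175 genes were higher and 3148 lower, 615 and 171 by at least 1 on the log2 scale. Libraries separated completely for 70.1% of genes (chance 10%). Of 369 genes under 0.5 FPKM in the siDNMT1 control, 287 were called higher, and of 81 under 0.5 FPKM with siCHD4 plus siDNMT1 19 were called lower. Both sets depend on the filter, and without it the counts were 1888 of 7100 and 66 of 6256.

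**Figure D2:**
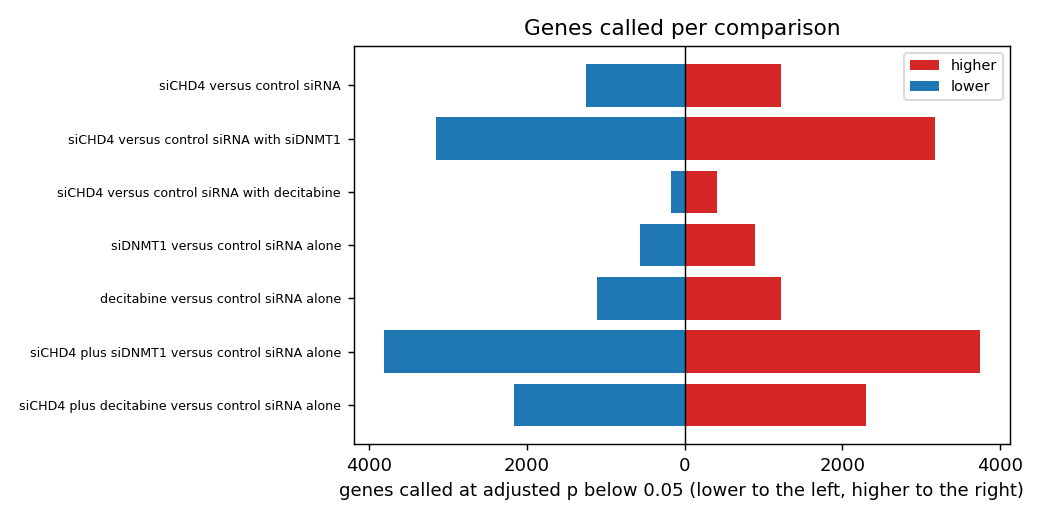
Numbers of genes called higher (bars to the right of 0) and lower (bars to the left of 0) by limma at adjusted p below 0.05 in the 7 comparisons of 3 against 3 libraries. The siCHD4 comparison called 2471 genes alone, 6323 with siDNMT1 and 586 with decitabine.

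With decitabine, siCHD4 again raised cancer-testis and germline genes. Of 39 tested, 29 rose and 0 fell (32 adjusted over the list alone; 31 and 0 of 74 without the filter), and the call held with an estimated correlation (camera adjusted p = 2.48e-35, and 0.00181 with an estimated correlation). MAGEB6 went from 0.0830 ± 0.0733 to 3.69 ± 0.837 FPKM and PAGE5 from 5.50 ± 0.657 to 23.3 ± 3.31 FPKM (log2 change 1.90, adjusted p = 8.64e-07). MAGEA4 went from 0.365 ± 0.102 to 5.03 ± 0.784 FPKM, MAGEA8 from 0.205 ± 0.0795 to 2.59 ± 0.235 FPKM and PAGE1 from 10.8 ± 5.87 to 63.1 ± 6.99 FPKM. TEX19 rose from 0.658 ± 0.767 to 16.0 ± 0.478 FPKM (log2 change 3.45, adjusted p = 1.31e-07) and LGALS1 from 5.87 ± 0.602 to 58.3 ± 6.54 FPKM. TKTL1 rose from 1.40 ± 1.22 to 15.8 ± 0.764 FPKM, BST2 from 5.44 ± 3.72 to 34.7 ± 3.72 FPKM and HCLS1, a haematopoietic signalling protein, from 0.784 ± 0.534 to 6.81 ± 0.367 FPKM. The receptor gene EDA2R, a p53 target, rose from 0.161 ± 0.0568 to 1.98 ± 0.0815 FPKM, and COL6A3 from 1.13 ± 0.564 to 6.86 ± 0.324 FPKM. LCN2, the iron-scavenging lipocalin-2, fell from 8.91 ± 0.496 to 2.56 ± 1.04 FPKM (log2 change -1.52, adjusted p = 2.11e-05), ELF5 from 19.2 ± 3.77 to 7.40 ± 1.37 FPKM and APOBEC3G from 9.23 ± 7.16 to 1.19 ± 0.164 FPKM. The decitabine control means of APOBEC3G, BST2, TEX19 and TKTL1 rest in part on replicate 0: without it they were 5.10, 3.30, 0.216 and 0.694 FPKM.

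Among other groups, 6 of 16 mesenchymal transition genes rose and 1 fell (7 and 1 adjusted over the list alone; adjusted p = 5.82e-05, and 0.114 with an estimated correlation). TNC changed by 1.38 and FN1 by 0.66. Neuronal genes rose in 3 of 12 cases (5 adjusted over the list alone; adjusted p = 0.00349, and 0.114 with an estimated correlation). BEX2 changed by 1.06 and UCHL1 by 0.73. The p53 targets rose in 3 of 33 cases (4 adjusted over the list alone; adjusted p = 0.0124, and 0.281 with an estimated correlation). Intestinal differentiation genes rose in 3 of 13 cases and fell in 1 (4 and 1 adjusted over the list alone; adjusted p = 0.0476, and 0.315 with an estimated correlation). KRT20 went from 0.308 ± 0.0997 to 3.74 ± 0.163 FPKM. Interferon-stimulated genes rose in 3 of 35 cases (6 adjusted over the list alone; adjusted p = 0.0418, and 0.329 with an estimated correlation). IFI27 changed by 1.71. DNA replication genes fell in 2 of 44 cases (11 adjusted over the list alone; adjusted p = 1.84e-11, and 0.281 with an estimated correlation). Mitotic genes fell in 2 of 32 (3 adjusted over the list alone; adjusted p = 0.000885, and 0.290 with an estimated correlation). The kinesin KIF2C changed by -0.46. Ribosomal protein genes had a median of -0.34 with 2 of 46 called lower (15 adjusted over the list alone; adjusted p = 1.76e-14, and 0.290 with an estimated correlation), and quantile normalization turned that median to 0.17. Histone genes had a median of -0.42 with 1 of 55 called lower (1 adjusted over the list alone; adjusted p = 2.68e-08, and 0.380 with an estimated correlation). ETS2 (0.71), CD44 (0.77) and EPHB2 (0.54) rose among 23 Wnt and stem cell genes, of which 1 fell (4 and 1 adjusted over the list alone; adjusted p = 0.167). Of 4 fibroblast markers 2 rose (3 adjusted over the list alone; 1 after quantile normalization), and of 6 blood cell markers 0 (2 adjusted over the list alone; adjusted p = 0.464). Removal of the GC trend called more genes: 10 DNA replication, 7 mitotic and 16 ribosomal protein genes lower, and 6 interferon-stimulated genes higher.

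This comparison called 418 genes higher and 168 lower, 99 and 14 by at least 1 on the log2 scale. Libraries separated completely for 27.1% of genes (chance 10%). Of 331 genes under 0.5 FPKM in the decitabine control, 116 were called higher, and of 135 under 0.5 FPKM with siCHD4 plus decitabine 1 was called lower (380 of 6965 and 5 of 6650 without the filter). Higher genes made up 71.3% of the calls as deposited and 56.6% after quantile normalization, and with the GC trend removed 470 were higher and 459 lower. The 586 calls became 295 and 301 without siCHD4 plus decitabine replicates 0 and 1. They became 306 with a filter at 5 FPKM, 147 in a fit on these 6 libraries alone, 3707 with library weights and 1366 without control siRNA plus decitabine replicate 0 and siCHD4 replicate 2.

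**Figure D3:**
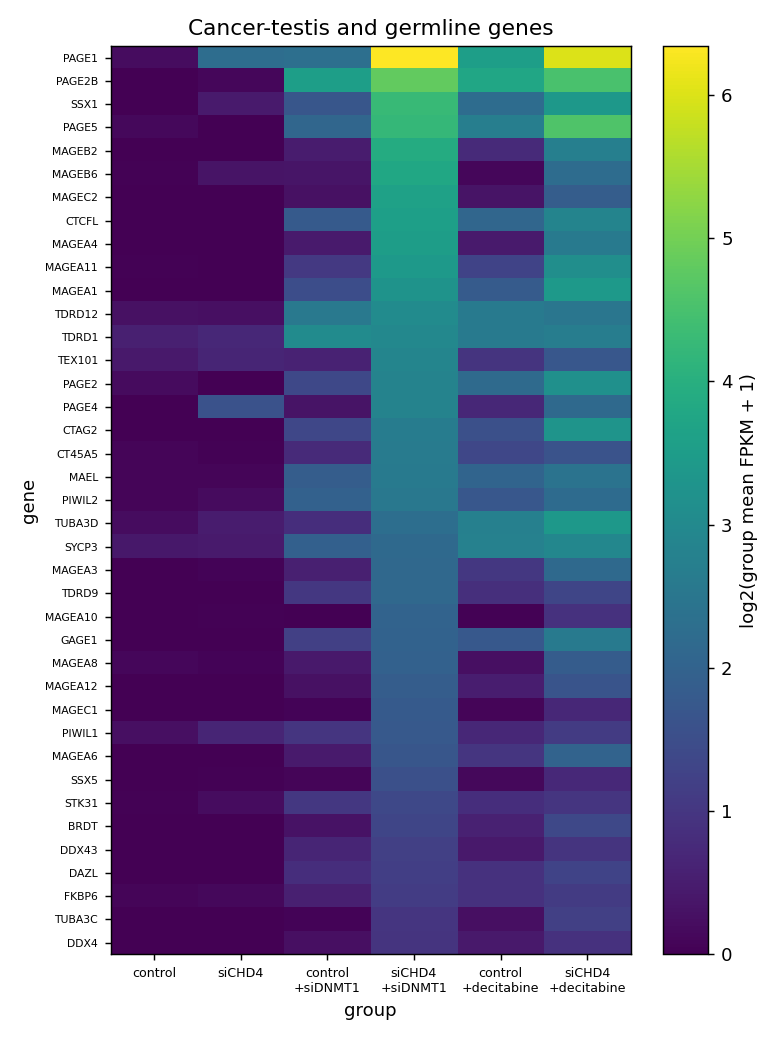
Heat map of log2(group mean FPKM + 1) for the 39 cancer-testis and germline genes tested, in the 6 groups (n = 3 libraries each). The number of these genes with a group mean of at least 1 FPKM was 0 with control siRNA, 2 with siCHD4, 17 with siDNMT1, 18 with decitabine, 37 with siCHD4 plus siDNMT1 and 33 with siCHD4 plus decitabine.

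The comparison of siDNMT1 with control siRNA alone asked what loss of DNMT1 did, but RNA was taken on day 11 against day 8, so treatment and schedule cannot be told apart. THBS1, the matrix glycoprotein thrombospondin-1 (chromosome 15, 39873280 to 39891667, plus strand), rose from 0.597 ± 0.0527 to 79.7 ± 1.27 FPKM (log2 change 5.66, adjusted p = 8.75e-17). Cancer-testis and germline genes rose in 23 of 39 cases with 0 lower (29 adjusted over the list alone; camera adjusted p = 3.17e-24, and 0.00469 with an estimated correlation). Without the filter, which partly fixes this result, 24 of 74 rose and 0 fell. PAGE5 went from 0.108 ± 0.188 to 3.24 ± 0.697 FPKM and the piRNA pathway gene TDRD1 from 0.477 ± 0.131 to 7.27 ± 0.420 FPKM. PIWIL2, of that pathway, went from 0.0539 ± 0.0486 to 2.95 ± 0.136 FPKM. The interferon-induced membrane proteins IFITM1 and IFITM2 rose from 2.46 ± 0.529 to 53.5 ± 0.633 FPKM and from 0.906 ± 0.414 to 13.7 ± 1.72 FPKM, within a list where 4 of 35 rose and 3 fell (4 and 4 adjusted over the list alone; adjusted p = 0.408). H19, an imprinted non-coding RNA (chromosome 11, 2016396 to 2025782, minus strand), rose from 3.66 ± 1.06 to 19.8 ± 2.46 FPKM (log2 change 2.18, adjusted p = 1.88e-08). Of the genes that fell, PRR15L went from 9.14 ± 1.15 to 1.69 ± 0.507 FPKM and the secreted protease inhibitor SLPI from 4.47 ± 1.32 to 0.927 ± 0.323 FPKM.

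Of 33 p53 targets 9 rose and 0 fell (18 adjusted over the list alone; adjusted p = 4.00e-07, and 0.0193 with an estimated correlation). TP53INP1 changed by 1.40 and TNFRSF10C by 1.02. Mesenchymal transition genes rose in 6 of 16 cases (10 adjusted over the list alone; adjusted p = 5.00e-06, and 0.0436 with an estimated correlation). S100A4 changed by 1.78 and vimentin VIM by 1.71. Cholesterol synthesis genes fell in 10 of 26 cases (13 adjusted over the list alone; adjusted p = 6.09e-06, and 0.00469 with an estimated correlation). The squalene epoxidase SQLE changed by -0.57 and STARD4 by -0.78. Histone genes rose in 15 of 55 cases with 0 lower (15 adjusted over the list alone; adjusted p = 0.000564, and 0.702 with an estimated correlation), although the list median was -0.04 against a mean of 0.99 and quantile normalization turned the median to 0.10. HIST1H2BG went from 0.152 ± 0.263 to 125 ± 13.0 FPKM (log2 change 6.79, adjusted p = 8.86e-09) and HIST1H1A from 0.327 ± 0.241 to 55.0 ± 2.84 FPKM. All 10 histone genes under 0.5 FPKM in the control rose, with a median log2 change of 4.48, whereas the 44 at 5 FPKM or more had a median of -0.11. DNA replication genes fell in 4 of 44 cases (3 adjusted over the list alone; adjusted p = 5.00e-06, and 0.441 with an estimated correlation). Of 8 genes often hypermethylated in colorectal cancer 3 rose (3 adjusted over the list alone; adjusted p = 0.0162, and 0.129 with an estimated correlation). Neuronal genes rose in 2 of 12 cases and fell in 1 (2 and 1 adjusted over the list alone; adjusted p = 0.0462, and 0.171 with an estimated correlation). UCHL1 changed by 1.94, and the list had a median of 0.11 that quantile normalization turned to -0.04. Of 23 Wnt and stem cell genes 4 rose and 2 fell (4 and 3 adjusted over the list alone; adjusted p = 0.393). The Wnt inhibitor APCDD1 went from 0.744 ± 0.211 to 9.09 ± 0.597 FPKM and NKD1 changed by 1.74. Stress genes of the endoplasmic reticulum list rose in 1 and fell in 4 of 24 cases (2 and 6 adjusted over the list alone; adjusted p = 0.0462, and 0.129 with an estimated correlation). Of 46 ribosomal protein genes 0 passed (0 adjusted over the list alone; adjusted p = 0.0462, and 0.728 with an estimated correlation). COL6A3, a fibroblast marker, rose from 0.0659 ± 0.0356 to 3.45 ± 0.198 FPKM, and 2 of 4 such markers were called. Of 6 blood cell markers 2 rose (3 adjusted over the list alone; adjusted p = 0.122), and 0 after quantile normalization. After quantile normalization 5 cholesterol synthesis genes, 2 DNA replication genes and 2 stress genes fell and 1 hypermethylated gene rose. With the GC trend removed 14 p53 targets rose, and 11 DNA replication genes and 8 stress genes fell.

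In this comparison 889 genes were higher and 563 lower, 264 and 13 by at least 1 on the log2 scale. Libraries separated completely for 41.6% of genes (chance 10%). Of 726 genes under 0.5 FPKM in the control 311 were called higher, and of 369 under 0.5 FPKM with siDNMT1 7 were called lower (486 of 7503 and 18 of 7100 without the filter). With the GC trend removed, over the 11499 genes with known GC content, more genes were lower (1245) than higher (959). The 1452 calls became 915 and 950 without control siRNA replicates 0 and 1, and 911, 890 and 917 without control siRNA plus siDNMT1 replicates 0, 1 and 2. They became 961 with a filter at 5 FPKM, 2774 in a fit on these 6 libraries alone, 4357 with library weights and 3518 without the pair of low-weight libraries of other groups.

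Decitabine compared with control siRNA alone, with RNA on day 5 against day 8 and therefore also confounded with schedule, raised p53 targets and cancer-testis genes. Of 33 p53 targets 24 rose and 0 fell (27 adjusted over the list alone; camera adjusted p = 2.18e-15, and 0.00121 with an estimated correlation). CDKN1A went from 22.8 ± 9.66 to 85.8 ± 15.4 FPKM (log2 change 1.92, adjusted p = 2.52e-05), the DNA damage binding protein DDB2 from 36.0 ± 5.97 to 70.1 ± 9.47 FPKM and SESN2 from 2.99 ± 0.215 to 6.73 ± 0.0900 FPKM. Cancer-testis and germline genes rose in 28 of 39 cases with 0 lower (31 adjusted over the list alone; adjusted p = 2.36e-26, and 0.00220 with an estimated correlation). Without the filter 27 of 74 rose and 0 fell, so this too is partly fixed by it. PAGE5 went from 0.108 ± 0.188 to 5.50 ± 0.657 FPKM and TDRD1 from 0.477 ± 0.131 to 5.12 ± 1.14 FPKM. H19 rose from 3.66 ± 1.06 to 75.8 ± 2.81 FPKM (log2 change 4.07, adjusted p = 2.03e-11) and CDKN1C, an imprinted cell cycle inhibitor, from 3.11 ± 0.891 to 20.2 ± 2.74 FPKM. SAP25, a SIN3 complex protein (chromosome 7, 100169851 to 100171523, minus strand), rose from 0.176 ± 0.172 to 40.0 ± 14.5 FPKM (log2 change 5.08, adjusted p = 2.36e-10). IFITM1 rose from 2.46 ± 0.529 to 36.3 ± 6.89 FPKM and BST2 from 0.102 ± 0.0885 to 5.44 ± 3.72 FPKM, where BST2 averaged 3.30 FPKM without decitabine replicate 0.

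Cholesterol synthesis genes fell in 15 of 26 cases with 0 higher (17 adjusted over the list alone; adjusted p = 3.67e-09, and 0.000832 with an estimated correlation). STARD4 went from 11.9 ± 1.92 to 4.28 ± 0.660 FPKM, INSIG1 from 24.5 ± 1.39 to 11.1 ± 0.894 FPKM and MSMO1 from 41.4 ± 1.22 to 22.3 ± 1.76 FPKM. Imprinted genes rose in 5 of 14 cases (5 adjusted over the list alone; adjusted p = 0.00774, and 0.180 with an estimated correlation). Mesenchymal transition genes rose in 8 of 16 cases (10 adjusted over the list alone; adjusted p = 9.00e-06, and 0.0508 with an estimated correlation). ACTA2 went from 2.43 ± 0.594 to 8.87 ± 2.73 FPKM and the collagen gene COL6A1 changed by 1.62. DNA replication genes fell in 12 of 44 cases and rose in 1 (13 and 1 adjusted over the list alone; adjusted p = 0.000167, and 0.661 with an estimated correlation). The cyclin CCNE2 changed by -0.69 and POLA1 by -0.49. Histone genes rose in 15 of 55 cases with 0 lower (15 adjusted over the list alone; adjusted p = 0.0197, and 0.922 with an estimated correlation), while the list median was -0.17 and the mean 0.91. HIST1H2BG went from 0.152 ± 0.263 to 147 ± 122 FPKM (log2 change 6.73, adjusted p = 1.14e-08) and HIST1H1B from 0.251 ± 0.282 to 52.7 ± 35.2 FPKM. Their values in decitabine replicates 0, 1 and 2 were 288, 75.9 and 77.9 FPKM for HIST1H2BG and 93.3, 33.7 and 31.1 FPKM for HIST1H1B. Replicate 0 thus raises these means, which were 76.9 and 32.4 FPKM without it. The 10 silent histone genes all rose (median 4.54), again partly fixed by the filter. The 44 abundant ones had a median of -0.25. HIST1H3C is listed at 0 in the 3 control siRNA libraries, at 87.1, 32.4 and 26.0 FPKM with decitabine and at 44.8, 49.8 and 40.5 FPKM with siDNMT1. Interferon-stimulated genes rose in 7 and fell in 6 of 35 cases (8 and 7 adjusted over the list alone; adjusted p = 0.913). The intestinal markers CA2, a carbonic anhydrase (-0.88), and DPP4 (-0.58) were lower and VIL1 (1.33) higher, in a list where 1 of 13 rose and 4 fell (4 and 5 adjusted over the list alone; adjusted p = 0.913). The Wnt inhibitor NKD1 rose from 2.12 ± 0.229 to 7.96 ± 0.335 FPKM. Of the markers of other cell types, 2 of 4 fibroblast markers rose (median 0.57; 2 adjusted over the list alone), a list too short to test, and 2 of 6 blood cell markers (median 0.26; 3 adjusted over the list alone; adjusted p = 0.113, and 0.209 with an estimated correlation). The latter were HBA1 (1.46) and CD68 (0.66). CD68 lost its call without control siRNA replicate 0 (adjusted p = 0.103), control siRNA replicate 1 (0.0685) or decitabine replicate 0 (0.104), and HBA1 without control siRNA replicate 1. After quantile normalization 1 gene of each of these lists rose. So did 4 mesenchymal transition and 3 imprinted genes, and 6 DNA replication and 4 histone genes fell. With the GC trend removed 5 mesenchymal transition genes rose and 3 interferon-stimulated genes fell.

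**Figure D4:**
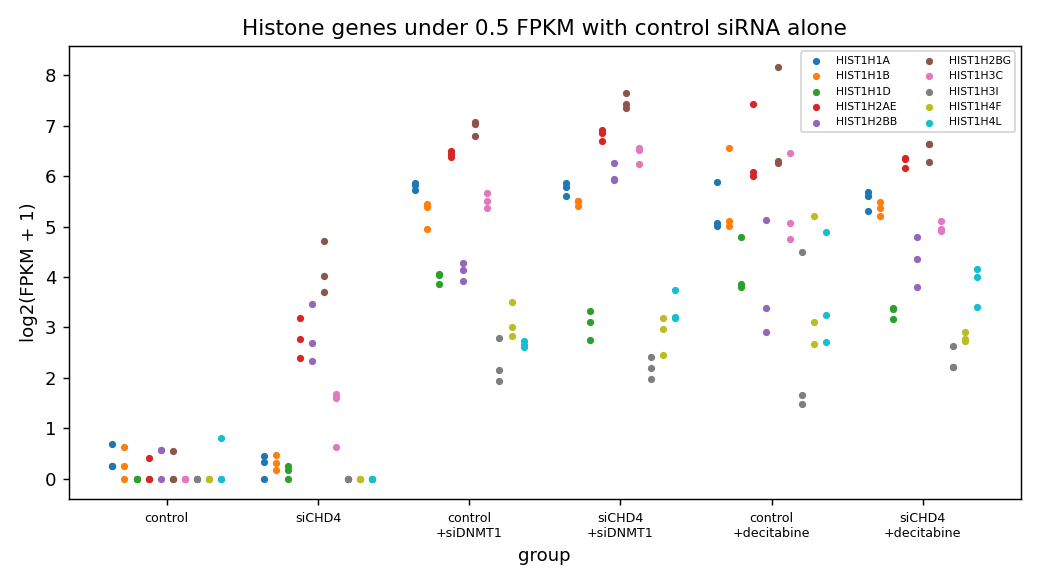
log2(FPKM + 1) of the 10 histone genes that averaged under 0.5 FPKM with control siRNA, in each of the 18 libraries (points) by group. Their median log2 change was 4.48 with siDNMT1, 4.54 with decitabine and 0.08 with siCHD4 alone.

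Decitabine called 1230 genes higher and 1105 lower, 261 and 25 by at least 1 on the log2 scale. Libraries separated completely for 34.5% of genes (chance 10%). Of 726 genes under 0.5 FPKM in the control 333 were called higher, and of 331 under 0.5 FPKM with decitabine 11 were called lower (519 of 7503 and 30 of 6965 without the filter). With the GC trend removed (11499 genes), 906 were higher and 1290 lower. The 2335 calls became 1519 and 1313 without control siRNA replicates 0 and 1. They became 929 in a fit on these 6 libraries alone, 5621 with library weights and 3548 without the pair of low-weight libraries.

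Both combinations were also compared with control siRNA alone, from which they differ in schedule too. Each called all 39 cancer-testis and germline genes tested higher (39 adjusted over the list alone in both; adjusted p = 4.38e-25 with siDNMT1 and 5.41e-37 with decitabine, and 0.00812 and 0.000732 with an estimated correlation). The filter admitted these genes largely through the groups where they are high, so 39 of 39 is nearly fixed by it. Of the 74 genes of the list 49 and 46 were called higher without the filter and 0 lower, and 10 are at 0 in all libraries. The summed FPKM of the 39 genes averaged 2.53 ± 0.714 with control siRNA, 10.03 ± 4.69 with siCHD4, 61.1 ± 2.95 with siDNMT1, 87.6 ± 30.4 with decitabine, 318 ± 16.3 with siCHD4 plus siDNMT1 and 247 ± 21.9 with siCHD4 plus decitabine (n = 3). HIST1H2BG rose from 0.152 ± 0.263 to 178 ± 20.8 FPKM with siCHD4 plus siDNMT1 and to 91.2 ± 12.5 FPKM with siCHD4 plus decitabine, and PAGE1 rose from 0.163 ± 0.142 to 63.1 ± 6.99 FPKM with siCHD4 plus decitabine. SNAR-I, a small non-coding RNA gene, is listed at 184.0, 100.1 and 209 FPKM with siCHD4 plus siDNMT1. It is at 30.4, 0 and 36.0 FPKM with siCHD4 plus decitabine and at 0 in the other groups. These values may rest on a few fragments. Mesenchymal transition genes rose in 15 of 16 cases with siCHD4 plus siDNMT1 (15 adjusted over the list alone; adjusted p = 1.63e-08, and 0.0177 with an estimated correlation) and in 12 of 16 with siCHD4 plus decitabine (12 adjusted over the list alone; adjusted p = 2.44e-08, and 0.0150 with an estimated correlation). DNA replication genes fell in 39 and 32 of 44 cases and rose in 1 in each (39 and 34 lower adjusted over the list alone; adjusted p = 7.52e-14 and 4.25e-11, and 0.144 and 0.215 with an estimated correlation). The p53 targets rose in 17 and fell in 6 of 33 cases with siCHD4 plus siDNMT1 (17 and 6 adjusted over the list alone; adjusted p = 0.00510, and 0.144 with an estimated correlation), and 2 fell after quantile normalization and 3 with the GC trend removed. They rose in 26 and fell in 0 with siCHD4 plus decitabine (27 adjusted over the list alone; adjusted p = 3.59e-13, and 0.00163 with an estimated correlation). With siCHD4 plus siDNMT1 3752 genes were higher and 3819 lower, and with siCHD4 plus decitabine 2308 and 2159. With the GC trend removed (11499 genes), these counts were 3035 and 4144, and 1762 and 2801. Of 726 genes under 0.5 FPKM in the control, 655 and 549 were called higher, and of 81 and 135 under 0.5 FPKM in the combinations 23 and 4 were called lower. The filter lets in most of these 726 through the groups where they are high, so the shares are partly fixed by it. Without it the counts were 2686 and 1409 of 7503, and 62 of 6256 and 24 of 6650. Library weights raised the calls with siCHD4 plus decitabine from 4467 to 7607.

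Markers of other cell types rose in the combinations as well. All 4 fibroblast markers measured were higher in each (4 adjusted over the list alone in both), with medians of 2.44 with siDNMT1 and 1.59 with decitabine, and this list is too short to test. Of 6 blood cell markers 5 rose with siCHD4 plus siDNMT1 (median 1.41; 5 adjusted over the list alone; adjusted p = 0.00867, and 0.0469 with an estimated correlation). With siCHD4 plus decitabine 3 rose (median 0.47; 3 adjusted over the list alone; adjusted p = 0.0738), and 0 after quantile normalization, where 2 fibroblast markers rose. Ribosomal protein genes fell in 42 and 27 of 46 cases with siDNMT1 and with decitabine (43 and 33 adjusted over the list alone; adjusted p = 1.11e-10 and 3.06e-08, and 0.377 and 0.421 with an estimated correlation). After quantile normalization 11 fell and 1 rose in the former, and 0 fell and 9 rose in the latter. Cholesterol synthesis genes fell in 18 and 19 of 26 cases and rose in 1 in each (18 and 19 lower adjusted over the list alone; adjusted p = 6.97e-05 and 1.72e-08, and 0.00969 and 0.000732 with an estimated correlation). Imprinted genes rose in 12 and 7 of 14 cases and fell in 2 and 1 (the same counts adjusted over the list alone; adjusted p = 0.000436 and 0.000707, and 0.0554 and 0.0654 with an estimated correlation). Neuronal genes rose in 10 and 6 of 12 cases and fell in 0 and 1 (the same counts adjusted over the list alone; adjusted p = 0.000220 and 0.00693, and 0.0186 and 0.0654 with an estimated correlation), where 6 rose with siDNMT1 after quantile normalization, and 3 rose and 3 fell with decitabine once the GC trend was removed. Mitotic genes fell in 13 and 10 of 32 cases and rose in 1 and 0 (13 and 10 lower adjusted over the list alone; adjusted p = 0.01004 and 0.00709, and 0.388 and 0.377 with an estimated correlation), and 6 and 2 fell after quantile normalization. Hypermethylated genes rose in 4 and 3 of 8 cases (4 and 3 adjusted over the list alone; adjusted p = 0.00944 and 0.0389, and 0.101 and 0.193 with an estimated correlation), and with decitabine 1 rose and 1 fell after quantile normalization, and 5 rose and 1 fell with the GC trend removed. Interferon-stimulated genes passed with siDNMT1, where 16 of 35 rose and 6 fell (16 and 6 adjusted over the list alone; adjusted p = 0.0362, and 0.377 with an estimated correlation). Wnt and stem cell genes passed with decitabine, where 8 of 23 rose and 1 fell (9 and 1 adjusted over the list alone; adjusted p = 0.0389, and 0.362 with an estimated correlation). Once the GC trend was removed 5 of these rose and 2 fell, with a median of 0.06 in place of 0.28.

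The differences between the siCHD4 effects were tested as interactions, and the schedules differ between the backgrounds too. The siCHD4 effect on cancer-testis and germline genes was higher with siDNMT1 than alone by a median of 1.35 on the log2 scale, with 27 of 39 genes called (33 adjusted over the list alone; adjusted p = 1.51e-39, and 0.00107 with an estimated correlation). With decitabine it was higher than alone by 0.71 with 16 called (27 adjusted over the list alone; adjusted p = 2.09e-25, and 0.00770 with an estimated correlation), and with siDNMT1 it exceeded that with decitabine by 0.44 with 12 called (13 adjusted over the list alone; adjusted p = 4.31e-08, and 0.104 with an estimated correlation). MAGEB2 (chromosome X, 30233680 to 30238206, plus strand) is listed at 0 in every control siRNA and siCHD4 library, at 0.293, 0.645 and 0.233 FPKM with siDNMT1 and at 13.1, 14.0 and 14.7 FPKM with siCHD4 plus siDNMT1 (adjusted p of the difference 4.19e-05). It is listed at 1.90, 0 and 0.205 FPKM with decitabine and at 5.99, 4.89 and 6.28 FPKM with siCHD4 plus decitabine (adjusted p = 0.0105). VCX, a testis-expressed X-linked gene, is also listed at 0 in those 6 libraries, at 0.271, 0.298 and 0.287 FPKM with siDNMT1 and at 14.9, 15.6 and 13.7 FPKM with siCHD4 plus siDNMT1 (adjusted p = 2.88e-08). TKTL1 responded more to siCHD4 with siDNMT1 (4.44, adjusted p = 4.17e-07) and with decitabine (2.88, adjusted p = 0.000158) than alone. The siCHD4 effect on HIST1H2BG, HIST1H2AE and HIST1H2BI was lower than alone with siDNMT1 (-3.46, -2.27 and -2.44) and decitabine (-4.37, -2.87 and -2.72). Between siDNMT1 and decitabine the siCHD4 effect differed for the tight junction gene CLDN6 (2.56), TEX19 (1.97), BST2 (2.01) and EHF (-1.24).

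The 3 differences called 528 genes (siDNMT1 minus alone), 148 (decitabine minus alone) and 1076 (siDNMT1 minus decitabine). The first count was 343 and 329 without control siRNA replicates 0 and 1, and 346 and 2557 without siCHD4 replicates 0 and 2. It was 332 and 343 without control siRNA plus siDNMT1 replicates 0 and 1, and 320 and 333 without siCHD4 plus siDNMT1 replicates 0 and 2. Higher genes made up 68.75% of these calls as deposited and 56.7% after quantile normalization. With the GC trend removed 357 were higher and 341 lower, and without the pair of low-weight libraries 1662 and 2210. The second count was 81 and 71 without control siRNA replicates 0 and 1, 303 without siCHD4 replicate 2, and 77, 81 and 88 without siCHD4 plus decitabine replicates 0, 1 and 2. The third was 343 and 359 without control siRNA plus siDNMT1 replicates 0 and 1, 643 and 320 without siCHD4 plus decitabine replicates 0 and 2, and 308 and 370 without siCHD4 plus siDNMT1 replicates 0 and 2. With library weights the counts were 6144, 2413 and 5626.

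The siCHD4 calls were compared between backgrounds, which share no libraries. Of the genes called for siCHD4 alone, 990 were also higher and 1035 also lower with siDNMT1, where independent lists would share 304 and 306, and TEX19, BST2, LGALS1 and PAGE1 were among those higher in both. With decitabine 192 higher and 98 lower calls were shared with siCHD4 alone (40.0 and 16.3 for independent lists; Fisher's exact p = 3.75e-87 and 5.17e-56), and 395 higher and 142 lower with siCHD4 on siDNMT1 (104 and 41.3; p = 2.24e-213 and 5.26e-61). Over all tested genes, which are not independent replicates, the siCHD4 changes alone and with siDNMT1 correlated with r = 0.515 (Spearman 0.733), alone and with decitabine with 0.258 (0.446), and with siDNMT1 and with decitabine with 0.459 (0.615). Small RNA genes pull these r values down, and without them they were 0.715, 0.489 and 0.685. Over genes called for siCHD4 alone the median absolute change was 0.597 with siDNMT1 and 0.198 with decitabine, and 86.9% of these genes had the same sign in the siDNMT1 and decitabine backgrounds. The 2025 calls shared by siCHD4 alone and with siDNMT1 became 1312 and 1279 without control siRNA replicates 0 and 1. The 290 shared by siCHD4 alone and with decitabine became 444 without siCHD4 replicate 2 and 140 and 144 without siCHD4 plus decitabine replicates 0 and 1, which also took the 537 shared by siCHD4 with siDNMT1 and with decitabine to 281 and 286.

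Calls of siDNMT1 and of decitabine, which share the control siRNA libraries, had 614 higher and 302 lower genes in common (85.4 and 48.6 for independent lists), among them PAGE5, TDRD1, IFITM1, IFITM2, H19 and HIST1H2BG, all higher in both, and 1 and 4 genes were called in opposite directions. Their log2 changes correlated across genes with r = 0.696 (Spearman 0.562), against a median of 0.490 for simulated unchanged groups that share a simulated control group. The covariance was 0.185 against 0.0400 simulated, a difference of 0.145, over 100 draws. The 3 control libraries are too few to be split, so part of the excess may come from the shared controls. The 916 shared calls became 594 and 577 without control siRNA replicates 0 and 1. Against the same controls, siCHD4 shared 221 higher and 176 lower calls with siDNMT1 and 366 and 446 with decitabine. Its log2 changes correlated with those of siDNMT1 with r = 0.307 and with those of decitabine with 0.423, both under the 0.490 of simulated unchanged groups, while the covariances (0.0705 and 0.106) were above the simulated 0.0400. Whether these overlaps reflect a shared response or the shared controls is left open.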

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

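All tests given here were chosen only after the result was seen, except the test of GC content and gene length for the decitabine library and the tests of differences between siCHD4 effects, which were planned.

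The following drew attention because the siCHD4 effect differed between backgrounds in a direct test. The difference was called for 528 genes (siDNMT1 minus alone), 148 (decitabine minus alone) and 1076 (siDNMT1 minus decitabine). The CHD4 transcript itself fell further with siDNMT1 than with decitabine (difference -0.77 on the log2 scale, adjusted p = 0.0289). On the log2(FPKM + 1) scale cancer-testis and germline genes responded more to siCHD4 with siDNMT1 (median difference 1.35) and with decitabine (0.71) than alone. So did the blood cell marker list with siDNMT1 (median 0.74). Of its 6 genes 2 were called for that difference (4 adjusted over the list alone; adjusted p = 0.00024, and 0.0162 with an estimated correlation). The schedule differs too and cannot be told apart from treatment in any of these. The filter partly fixes the cancer-testis values.

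Regrouping the libraries tested the counts, and the regroupings for the differences were drawn again once after their definition was changed. For the differences, 8, 11 and 13 of 100 regroupings, the real one included, called as many genes as the real 528, 148 and 1076. The highest other regroupings called 5110, 3105 and 5957 genes. These, and 7, 9 and 12 of the regroupings as large, kept the real groups in 1 background, so they carry the siCHD4 effect of that background into the difference by construction and are no measure of chance. Of those that broke the groups in both backgrounds 0, 1 and 0 were as large, and their highest counts were 1, 586 and 1. The 586, several times the real 148, points to a structure of the samples in the second difference. This test leaves chance undecided for the differences. For the 7 comparisons of 3 against 3 libraries, the real grouping was the 1 of 10 with the most calls in each, and 10 regroupings are too few for a share under 0.05. The real counts were 2471 (siCHD4 alone), 6323 (with siDNMT1), 586 (with decitabine), 1452 (siDNMT1), 2335 (decitabine), and 7571 and 4467 (combinations with siDNMT1 and with decitabine against control siRNA). The highest other counts were 217, 0, 0, 1, 1, 1 and 0. The 217 came from setting control siRNA replicates 0 and 1 with siCHD4 replicate 2.

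The first pattern is 1 library, control siRNA plus decitabine replicate 0, whose values stood apart from its group (residual SD 0.471, library weight 0.0923). The worth of 1 fragment was 2.04 higher on the log2 scale than in control siRNA replicate 0, against at most 0.16 in the other libraries, so a lower depth may contribute. With the trend in GC content and gene length removed, its residual SD over genes with a length went from 0.324 to 0.270, against at most 0.277 in the other libraries. GC bias cannot be told apart from this, because residuals in a group of 3 are centred, which ties the GC correlation of 0.54 in this library to that of -0.58 in replicate 1. No biological explanation was tested.

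The second pattern is the lower number of siCHD4 calls with decitabine (586) than with siDNMT1 (6323). The shallow library alone is argued against as the whole cause: without it, the median absolute log2 change over the genes called for siCHD4 alone was 0.224, against 0.597 with siDNMT1. A weaker depletion of CHD4 with decitabine (difference -0.77) may contribute. The time from siCHD4 to RNA was the same with decitabine (days 1 and 2 to day 5) and siDNMT1 (days 7 and 8 to day 11). This argues against that time as a cause. The timing of siCHD4 relative to the background treatment differed and cannot be told apart from the background. An effect of decitabine on the response to CHD4 loss stays open and untested.

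The third pattern is the rise of 10 histone genes that averaged under 0.5 FPKM in the control, all called higher both with siDNMT1 and with decitabine. Reads shared with abundant copies of the same class (5 FPKM or more in the control) cannot be told apart. Of 23 abundant H1, H2A and H4 genes 0 were called higher, but the classes were split by that outcome. Their highest log2 change was 0.40, against a lowest of 2.39 in the 6 silent ones. A small share of an unchanged copy's reads could raise a silent gene. For H2B and H3 (4 silent genes), 4 of 21 abundant genes were called higher with each treatment, by up to 3.83. With siCHD4 alone 4 of the 10 silent genes were called higher as well, and reads shared among the genes that rose were not tested. All 10 rose with RNA taken later (siDNMT1) and earlier (decitabine) than in the control. No such RNA was taken on the control's day, so another schedule cannot be told apart. Loss of DNA methylation at these genes could be a cause, as a hypothesis, and methylation was not measured.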

How the results depend on the processing

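Leaving out the pair of low-weight libraries, removing the GC trend and leaving out small RNA genes were alternatives chosen after seeing the data, and the others were planned. Of 6865 values of the 402 named gene results under the alternatives, 6340 (92.4%) kept their direction and their side of the threshold and 525 (7.65%) kept their direction but lost the call, with 0 turning direction. These shares hide how many single calls were lost at least once. Under another setting 34 of 67 named results for siCHD4 alone, 11 of 95 with siDNMT1, 34 of 60 with decitabine, 11 of 62 for siDNMT1 and 26 of 68 for decitabine lost the call. With a library left out 8, 6, 27, 15 and 17 did, in the same order. Of 10 named results each for siCHD4 plus siDNMT1, siCHD4 plus decitabine and the 3 differences, 0, 2, 0, 2 and 4 lost the call under another setting and 0, 4, 0, 0 and 2 with a library left out. The fit on the compared groups only lost 88 of the 402 and quantile normalization 34. Counts are given where they moved by more than 1.5 times, and the cause was not tested unless stated. Rescaling by the median ratio and leaving out small RNA genes moved none of the counts that far. No scaling moved the median of all genes by more than 0.1 on the log2 scale.

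With a pseudocount of 0.1 the difference of siDNMT1 and siCHD4 alone called 317 genes in place of 528, and that of siDNMT1 and decitabine 693 in place of 1076. With no filter on low values the former called 1093. Genes under 0.5 FPKM in the control and called higher, which were 119, 287 and 116 for siCHD4 alone, with siDNMT1 and with decitabine, 311 and 333 for siDNMT1 and decitabine, and 655 and 549 for the combinations with siDNMT1 and with decitabine, became in that order 247, 1888, 380, 486, 519, 2686 and 1409 with no filter, because more low genes are tested. A filter at 5 FPKM tests fewer low genes and gave 26, 21, 11, 87, 91, 122 and 116. A limit of 0.1 FPKM admits fewer genes and gave 38, 62, 36, 172, 193, 333 and 311, and a limit of 1 FPKM gave 200, 593 and 180 for the first 3. With quantile normalization these counts were 65 for siCHD4 alone, 62 with decitabine, 195 for siDNMT1, 198 for decitabine and 318 for siCHD4 plus decitabine.

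The filter at 5 FPKM also left 306 calls for siCHD4 with decitabine (586), 961 for siDNMT1 (1452), 219 for the difference of siDNMT1 and siCHD4 alone (528) and 83 for that of decitabine and siCHD4 alone (148). Calls shared by siCHD4 alone and with decitabine were 192 in place of 290, those with siDNMT1 and with decitabine 285 in place of 537, and those of siDNMT1 and decitabine 608 in place of 916. With the replicate number as a block, the difference of decitabine and siCHD4 alone called 97 genes and that of siDNMT1 and decitabine 692, although the numbers do not pair the libraries.

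Library weights raised most counts: 5904 for siCHD4 alone (2471), 3707 with decitabine (586), 4357 for siDNMT1 (1452), 5621 for decitabine (2335) and 7607 for siCHD4 plus decitabine (4467), and 6144, 2413 and 5626 for the differences (528, 148 and 1076). Silent genes called higher were 195 for siCHD4 alone and 188 with decitabine. Shared siCHD4 calls were 4039 alone and with siDNMT1 (2025), 2029 alone and with decitabine (290) and 3276 with siDNMT1 and with decitabine (537), and siDNMT1 and decitabine shared 2883 (916). A fit on the compared groups only, which has fewer residual degrees of freedom, gave 514 calls for siCHD4 alone, 147 with decitabine, 2774 for siDNMT1, 929 for decitabine, 42 for the difference of decitabine and siCHD4 alone and 1906 for that of siDNMT1 and decitabine. Silent genes called higher were then 65 for siCHD4 alone, 56 with decitabine and 208 for decitabine, and the shared siCHD4 calls 466, 53 and 143.

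Without control siRNA plus decitabine replicate 0 and siCHD4 replicate 2, the pair with the lowest weights, siCHD4 with decitabine called 1366 genes, siDNMT1 3518, decitabine 3548, and the differences 3872, 477 and 2889. Silent genes called higher with siCHD4 on decitabine were 181. Calls shared by siCHD4 alone and with decitabine were 710, those with siDNMT1 and with decitabine 1273, and those of siDNMT1 and decitabine 2101. With the GC trend removed, over 11499 genes, siCHD4 with decitabine called 929 genes, siDNMT1 2204 and the difference of decitabine and siCHD4 alone 235. Shared calls were 492 for siCHD4 alone and with decitabine and 832 with siDNMT1 and with decitabine.

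The CHD4 change with decitabine (-0.46, adjusted p = 0.0752) kept its direction and passed the threshold with library weights (-0.54, adjusted p = 5.24e-05), without the pair of low-weight libraries (-0.55, adjusted p = 0.00155) and with the GC trend removed (-0.51, adjusted p = 0.0329). With single libraries left out it ranged from -0.55 (adjusted p = 0.0449, without control siRNA plus decitabine replicate 0) to -0.41. The CHD4 changes in the other backgrounds and the DNMT1 changes with siDNMT1 kept their calls under all alternatives.

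With single libraries left out, the counts ranged from 1484 to 2580 for siCHD4 alone, 295 to 641 with decitabine, 890 to 1091 for siDNMT1 and 1313 to 2341 for decitabine, and from 320 to 2557, 71 to 303 and 308 to 1475 for the differences. Shared siCHD4 calls ranged from 1279 to 2197 alone and with siDNMT1, 140 to 444 alone and with decitabine and 281 to 600 with siDNMT1 and with decitabine, and those of siDNMT1 and decitabine from 577 to 1120. The report names the libraries behind these moves.

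With an estimated correlation in place of the preset one, the number of lists that passed went from 6 to 0 for siCHD4 alone, from 11 to 2 with siDNMT1, 10 to 1 with decitabine, 10 to 4 for siDNMT1, 7 to 3 for decitabine, 12 to 5 and 11 to 4 for the combinations, and 11 to 2, 4 to 1 and 9 to 0 for the differences. With fry, 17 lists passed for siCHD4 with siDNMT1 and 1 for the difference of decitabine and siCHD4 alone. Depth limits the low genes most, above all in control siRNA plus decitabine replicate 0.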

Other observations

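No test is given in this part.

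HBE1, an embryonic globin gene, is listed at 0 in every control siRNA library, at 2.73, 3.34 and 1.81 FPKM with siCHD4, at 6.23, 7.89 and 7.64 FPKM with siCHD4 plus decitabine and at 13.2, 10.6 and 10.9 FPKM with siCHD4 plus siDNMT1. SNORD33, a small nucleolar RNA gene, is listed at 2986, 3196 and 5982 FPKM in the control siRNA libraries. It is listed at 0 in all libraries with siCHD4, siDNMT1 and siCHD4 plus siDNMT1, at 0, 0 and 2727 FPKM with decitabine and at 1811, 0 and 0 FPKM with siCHD4 plus decitabine. The worth of 1 fragment relative to control siRNA replicate 0 was 1.07 in control siRNA replicate 1 and 0.607 in siCHD4 plus decitabine replicate 0. The 3196 and 1811 FPKM stand to the 2986 FPKM in about these ratios, so the SNORD33 values may rest on 1 or a few fragments. MTRNR2L2 is listed at 69323 FPKM in control siRNA plus decitabine replicate 0 and at 20.2 to 2406 FPKM in the other libraries.

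Across 11313 genes, which are not independent replicates, the log2 changes correlated with GC content with Spearman values of 0.29 for siCHD4 alone, 0.31 with siDNMT1, -0.12 with decitabine, -0.09 for siDNMT1 and 0.45 for decitabine. For the differences between siCHD4 effects the values were 0.19 for siDNMT1 and siCHD4 alone, -0.42 for decitabine and siCHD4 alone, and 0.48 for siDNMT1 and decitabine.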
